A study of Mus musculus with 2 samples.

How the data were processed

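Pancreatic cells of 2 single-cell RNA libraries were compared. Per the labels, 6-week-old KC mice and KC mice that also carry Ccr1-/- received caerulein, a secretagogue that injures acinar cells, at 250 µg/kg daily for 5 days, and pancreata were taken 3 weeks later. The KC library came from 1 female mouse and the KC;Ccr1-/- library from 2 female mice pooled, both with the same run date. Tissue was digested with Collagenase V at 1 mg/mL for 30 min, passed through strainers down to 40 µm and enriched for live cells by removal of dead ones.

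The deposited files hold raw UMI counts per gene and barcode, made, per the labels, by Cell Ranger 6.1.0 on the mm10 genome, and were not normalised. They hold only barcodes that Cell Ranger kept as cells, with 32285 features. Each barcode has at least 500 UMIs. Chemistry and intron counting are not given in the sources used here. The KC file has 5370 barcodes with 66655671 UMIs and the KC;Ccr1-/- file 6491 barcodes with 118101281 UMIs.

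Barcodes with at least 500 UMIs, at least 200 genes and at most 15% mitochondrial UMIs were kept. Under 200 genes were 431 KC barcodes and 826 of the other library, and a further 399 and 1225 lay over the mitochondrial limit. Doublets were called in each library by Scrublet, as run in Scanpy, with an expected rate of 0.05, and 62 and 70 were removed. This left 4478 cells with 61822712 UMIs and 4370 cells with 108692191 UMIs.

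Values were scaled to 10000 UMIs per cell and log-transformed. Both libraries were clustered together, without integration, on 2000 variable genes, 30 principal components and a shared-neighbour graph with 15 neighbours, by the Leiden method at resolution 1.0, which gave 26 clusters. Clusters were named from marker genes fixed before the data were examined, so every class name means cells like that type by those markers. A cluster led by cell cycle genes, or with few UMIs and no marker among its 10 leading genes, stayed without a name. T cells were clustered again with 20 components to name subsets.

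UMIs were summed over the cells of each class in each library and given as CPM with exact Poisson 95% intervals. Ratios are log2 of KC;Ccr1-/- over KC with a prior of 0.5 counts scaled to library size and an exact conditional binomial interval. Shares of cells have exact Clopper-Pearson intervals. A count of 0 is read against a floor of 3 counts over the class. Shares of cells with a UMI were also computed after thinning each cell to 3000 UMIs, which leaves out cells with fewer. With 1 library per group no test was run.

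Classes with at least 50 cells in each library were compared. Macrophages, with 28 KC cells, were compared as an exception with a minimum of 20, made after the cell numbers were seen. Dendritic, endothelial, mesothelial, plasma and innate lymphoid cells were left out of the gene lists and the ranking of genes because at least 1 of the libraries held fewer than 50. Only Ccr1, ligands of CCR1 and single genes looked up later are given for them.

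Gene lists fixed before the data were examined were summarised by the median log2 ratio of members with at least 10 UMIs in the class, with an interval from 1000 Poisson redraws. Each median was placed among 10000 random lists matched on expression, as a description of these libraries. The lists cover ribosomal protein, mitochondrially encoded, acinar, and dissociation and stress genes, neighbours of Ccr1 on chromosome 9, interferon response, MHC class I and II, complement, inflammatory cytokines and NF-kB targets, chemokines that bind CCR1, chemokine receptors, glycolysis and hypoxia, and cell cycle. Other lists cover macrophage, neutrophil, T cell, epithelial and fibroblast programmes.

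Genes named in the text are the 10 highest and 10 lowest log2 ratios of each class, or members of those lists. The rule asked for at least 100 UMIs in the class, a UMI in at least 5% of the class's cells and a CPM of at least 0.2 of the gene's highest class. It left out mitochondrial, ribosomal protein, immunoglobulin, T cell receptor, haemoglobin, Gm, Rik, Xist and Y-linked genes. The text gives part of the named genes of each class. Clock genes and Ins2 were looked up after the values were seen.

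The ratio and its interval were tested on simulated data, drawn as Poisson counts of class totals without variation between animals or between cells. In these data 100 genes per size and class were given a log2 change of 1 or 2. For a change of 1, 80% of the genes were called the right way in macrophages (4211 genes run), 97% in T cells (6218), 98% in neutrophils (3898), 99% in the epithelium (11066) and in fibroblasts (12730), and 100% in tuft cells (5630) and B cells (1238). For a change of 2 the share was 99% in macrophages and 100% in each of the other classes. Intervals held the true value in 93% to 99% of changed genes. These shares cover counting error only. They cannot show how the intervals do where single cells hold much of a gene's UMIs, as in the macrophages.

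Alternatives were edgeR's TMM and DESeq2's size factors, equal weight for each cell or each cluster, a total without acinar, mitochondrial and ribosomal protein genes, other UMI minimums and a prior of 5 counts. For the cells, no removal of doublets, mitochondrial limits of 10% and 25%, a minimum of 500 genes, Leiden resolutions of 0.5 and 2.0, centring per library, naming cell by cell, shares of immune cells and shares of cells other than fibroblasts were tried. DESeq2's factors moved all ratios by -0.12 in neutrophils and 0.11 in macrophages. The tools were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, Scanpy 1.11.5, leidenalg 0.10.2, python-igraph 0.11.9, Matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.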

Results

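Single-cell RNA sequencing compared the pancreas of KC mice (Ptf1a-Cre;LSL-KrasG12D, which form PanIN, the precursor lesions of pancreatic cancer) with that of KC mice whose label adds loss of Ccr1, a receptor for inflammatory chemokines on myeloid cells. Pancreatitis was induced with caerulein in both, and the tissue was taken 3 weeks later. The KC library came from 1 female mouse and the library labelled KC;Ccr1-/- from 2 pooled female mice, so each group is 1 library. There are no replicates, and the intervals given cover counting error only. The files held 5370 barcodes with 66655671 UMIs for KC and 6491 barcodes with 118101281 UMIs for KC;Ccr1-/-. After filtering, 4478 and 4370 cells remained, with medians of 10467.5 and 16702.5 UMIs. Barcodes over the mitochondrial limit made up 15.3% of the KC library and 31.4% of the library labelled KC;Ccr1-/-. Cell classes carry the names of their markers (macrophage-like, neutrophil-like and so on, written below without the suffix).

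Does the label match the targeted gene? Ccr1 (ENSMUSG00000025804, GRCm38 chromosome 9, 123962124 to 123968692) was lower but still present in the library labelled KC;Ccr1-/-. Neutrophils, the class with the highest level, held 658 CPM in KC (1113 UMIs, interval 620 to 698) and 333 CPM in the other library (649 UMIs, interval 308 to 360), a log2 ratio of -0.98 (interval -1.12 to -0.84). Ccr1 was seen in 79.9% of KC neutrophils and 68.8% of those in the other library, or 78.3% and 58.1% after thinning each cell to 3000 UMIs, which left out 124 and 102 shallower cells. Median depths of neutrophils were 4276.5 and 4075 UMIs. Macrophages held 142 CPM (59 UMIs) and 42.7 CPM (134 UMIs), a log2 ratio of -1.73 (interval -2.19 to -1.27). A Ccr1 UMI was seen in 50% and 45.7% of macrophages, or 18.5% and 10.9% after thinning, at median depths of 13087 and 16509 UMIs. T cells held 10.2 and 1.73 CPM, dendritic cells 46.0 and 10.5 CPM, and tuft cells 2.65 and 1.26 CPM. B cells had 2 Ccr1 UMIs in each library. The epithelium had 0 Ccr1 UMIs in 192 KC cells, which allows up to 0.264 CPM, and 0.396 CPM in the other library. Fibroblasts, which should lack the receptor, carried a Ccr1 UMI in 0.238% of KC cells and 0.993% of KC;Ccr1-/- cells, at median depths of 11820 and 23175 UMIs. After thinning, those shares were 0.141% and 0.0966%. Neither the structure of the targeted allele nor the chemistry is given in the sources used here. Reads that fall outside a deleted part check nothing, so these counts neither bear out nor refute the label. The name "the library labelled KC;Ccr1-/-" is therefore used below, and each direction is a difference between these 2 libraries.

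**Figure D1:**
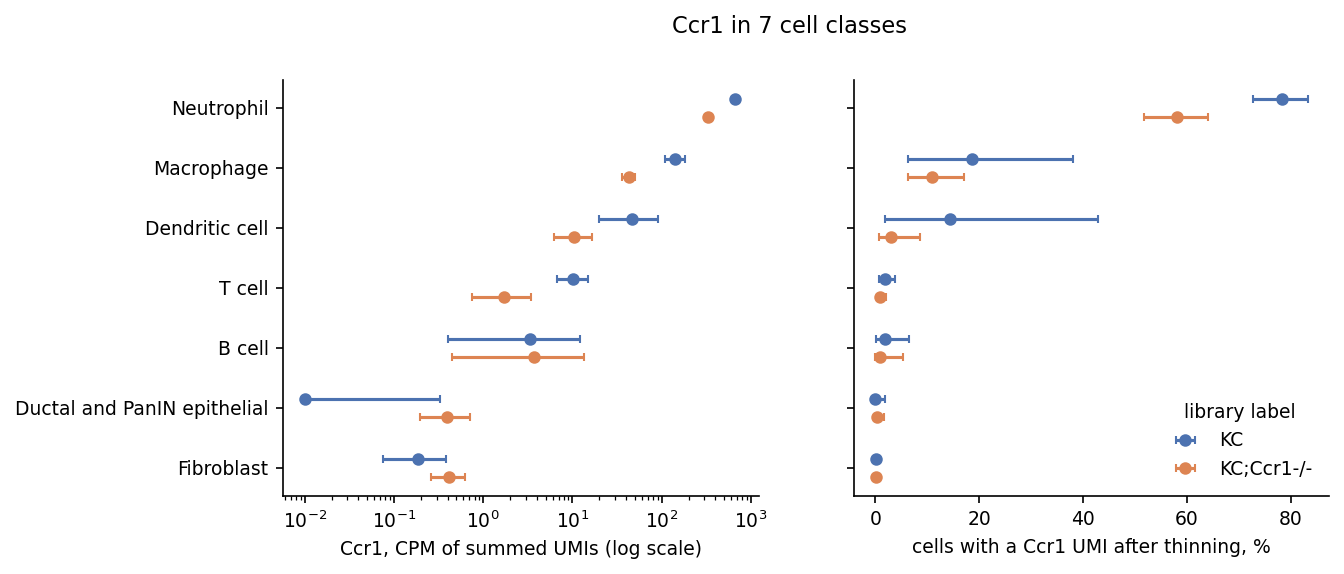
CPM of summed UMIs on a log axis (left, exact Poisson 95% intervals, with values and bounds under 0.01 drawn at 0.01) and percent of cells with a Ccr1 UMI after thinning to 3000 UMIs (right, exact binomial 95% intervals) are plotted for 7 cell classes. Neutrophils carry the most Ccr1 in both libraries, 658 CPM in KC and 333 CPM in the library labelled KC;Ccr1-/-.

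Which cells made up each pancreas? Macrophages took 0.625% of kept KC cells (28 cells, interval 0.416% to 0.902%) and 3.46% of cells in the library labelled KC;Ccr1-/- (151 cells, interval 2.93% to 4.04%), 5.53-fold more (interval 3.67 to 8.59). Dendritic cells took 0.357% and 2.38%, 6.66-fold more, and endothelial cells 0.983% and 4.07%, 4.15-fold more. Tuft cells, chemosensory cells of metaplastic epithelium, were 2.81-fold fewer (interval 2.03 to 3.95), 3.28% against 1.17%. Neutrophil shares were close, 8.44% and 8.28%.

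Other classes differed less. Ductal and PanIN epithelial cells made up 4.29% of KC cells and 8.31% of the other library, and T cells 9.83% and 14.5%. Fibroblasts, the main class, took 65.8% and 48.4%. B cells took 3.15% and 2.63%, plasma cells 0.603% and 1.10%, innate lymphoid cells 0.871% and 0.961%, and mesothelial cells 0.893% and 1.72%. Of the immune cells alone, macrophages made up 2.62% and 10.4% and dendritic cells 1.50% and 7.14%. By that measure neutrophils lay lower, 35.4% and 24.8%, as did B cells, 13.2% and 7.89%, while T cells took 41.2% and 43.6%. Of the cells other than fibroblasts, a base chosen after the data were seen, the log2 ratio was 1.87 for macrophages, 2.14 for dendritic cells, 1.46 for endothelial cells, 0.36 for the epithelium, -0.028 for T cells, -0.62 for neutrophils, -0.85 for B cells and -2.08 for tuft cells. Among endothelial cells the difference lay mostly in cluster 13, which held 17 KC cells and 142 of the other library, while lymphatic-marker cluster 22 held 27 and 36. Clusters left without a name held 41 and 131 cells. 1 of these, with few UMIs per cell, scored highest for macrophage markers and had 31 and 77 cells, and a cycling cluster, which scored highest for fibroblast markers, had 10 and 54. With 1 preparation per group and no acinar cluster in either, shares reflect what each digestion released as well as the tissue.

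**Figure D2:**
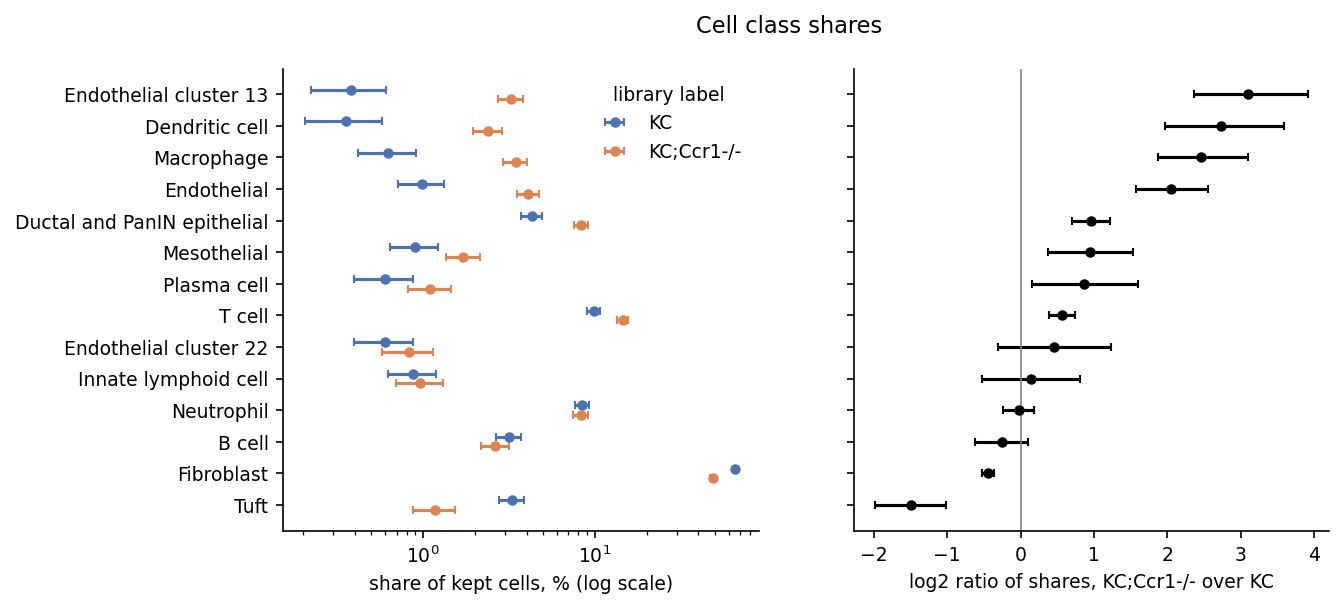
Percent of kept cells in each library on a log axis (left, exact binomial 95% intervals) and log2 ratio of the shares, KC;Ccr1-/- over KC (right, exact 95% intervals), are plotted for each cell class. Endothelial cluster 13 (3.10), dendritic cells (2.74) and macrophages (2.47) lie farthest to the right, and tuft cells (-1.49) farthest to the left.

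How did macrophages differ? Macrophages of the library labelled KC;Ccr1-/- held more transcripts of inflammatory mediators and less of genes typical of tissue-resident cells, while the immunosuppressive genes fixed beforehand went both ways. Only 28 KC cells, with 414630 UMIs, stand behind the KC values. That is under the fixed minimum of 50, so this class was compared as an exception made after its cell numbers were seen.

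The list of inflammatory cytokines and NF-kB targets had a median log2 ratio of 0.61 (interval 0.47 to 0.84; 13 of 17 measured members above 0), higher than every one of 10000 matched random lists. Its median was 1.55 with the mitochondrial limit at 10% and reached 0.91 with 1 KC cell left out, and mitochondrially encoded genes were higher in these cells too (0.39, 12 of 12 above). Il1b, which encodes interleukin 1 beta, had 437 and 8378 UMIs, a log2 ratio of 1.34. Osm (2.58) and Ptgs2 (1.81), which encodes cyclooxygenase 2, were higher too, while Il1a (-1.25, with 42.5% of KC UMIs from 1 cell) and Tnf (-0.65) were lower, Tnf standing at 0.41 with the mitochondrial limit at 10%. Genes of glycolysis and hypoxia had a median of 0.58 (15 of 17 above), complement genes 0.29 (11 of 14 above) and chemokines that bind CCR1 0.36 (6 of 8 above).

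Among the immunosuppressive macrophage genes, 5 of 15 lay above 0 and 10 below, with a median of -0.33 (interval -0.63 to 0.07; percentile 1.10 of matched random lists). Arg1, the arginase of alternatively activated macrophages, had a log2 ratio of 1.54 (interval 1.14 to 1.98). It was seen in 14.3% and 47.7% of cells, or 14.8% and 26.5% after thinning, and 1 cell held 51.0% of its KC UMIs. Chil3 (-3.41) and Retnla (4020 and 1008 CPM), other genes of that state, were lower, but 80.7% of KC Chil3 UMIs and 44.4% of KC Retnla UMIs came from 1 cell each. Mrc1 (0.04) and Cd274 (-0.26, interval -1.12 to 0.71), which encodes PD-L1, differed by no more than their intervals, but Mrc1 was at 0.72 (interval 0.34 to 1.12) without the cells that carried fibroblast transcripts. With the mitochondrial limit at 10%, which gave a macrophage class of 45 and 184 cells, the median of this list was 0.50.

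Tissue-resident macrophage genes had a median of -1.82 (interval -2.06 to -1.14; 1 of 12 above, below all matched random lists), with summed CPM of 1997 and 1133. The scavenger receptor gene Cd163 (29 and 9 UMIs, -4.48), Lyve1 (27 and 4 UMIs, -5.39) and F13a1 (-2.33) were all lower, but 1 KC cell held 88.9% of the Lyve1 UMIs and 1 held 48.3% of those of Cd163. Leaving out 1 KC cell could bring the median to -0.73, and leaving out cells with fibroblast transcripts brought it to -0.59. Monocyte genes had a median of -0.26 (4 of 12 above) but summed CPM of 7313 and 8450, and lipid-associated genes had one of -0.02 (8 of 16 above), with Spp1 at 1.32 (67.3% of KC UMIs from 1 cell) and Gpnmb at -3.12 (85.7% of KC UMIs from 1 cell). Genes of MHC class II had a median of -0.23, MHC class I -0.55 (0 of 13 above) and interferon response -0.60 (6 of 22 above). Leaving out 1 KC cell could bring MHC class I to -0.27. Chemokine receptors had a median of -0.66 (0 of 6 above), Ccr1 included. With the mitochondrial limit at 10%, the medians lay above 0: 0.81 for MHC class II, 0.43 for MHC class I, 0.17 for interferon response, 0.36 for chemokine receptors and 0.85 for monocyte genes.

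Among the genes named by the fixed rule, the higher side was led by stromal transcripts. F3 had 0 KC UMIs and 114 in the other library, at least 5.02-fold higher. Ptx3 (4.12, interval 1.77 to 9.58), Timp1 (3.37), Kng2 (3.33), Serpina3n (3.26), Sfrp2 (3.17), Mmp3 (2.71) and Plpp3 (2.63) were higher. 1 cell held 95.7% of the KC UMIs of Mmp3. In both libraries some macrophage droplets carried fibroblast RNA: 6 of 28 and 34 of 151 cells had at least 20 UMIs of the fibroblast markers, and these held 98.0% and 97.4% of the class's fibroblast-marker UMIs. Without those cells Plpp3 lay on the other side of 0 (5 and 5 UMIs, -2.66, interval -4.98 to -0.74). Sfrp2 (1 and 2 UMIs, -1.50) and Mmp3 (1 and 3 UMIs, -1.07) then had intervals that included 0. Ptx3 then kept 0 and 3 UMIs, F3 0 and 14, Kng2 0 and 8 and Serpina3n 0 and 6, too few to give a direction. Timp1 then had a log2 ratio of 2.20, but the remaining macrophages still held 137 and 327 CPM of the fibroblast markers. Hbegf, a growth factor of the EGF family (3.55, interval 1.75 to 6.68), the adhesion protein gene Jaml (3.15), Il1b (1.46) and Osm (2.75) stayed higher, and Chil3 (-3.36), Retnla (-2.31) and F13a1 (-1.86) stayed lower. In all cells, Hbegf stood at 3.69, Jaml at 2.97, Gdpd3 at -2.26 and Lyz1 at -2.24. Of KC Lyz1 UMIs 81.5% came from 1 cell, and its ratio was 0.023 without removal of doublets, 1.20 with the mitochondrial limit at 10% and 0.11 with centring per library.

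How did neutrophils differ? Interferon response genes were higher in neutrophils of the library labelled KC;Ccr1-/-, while inflammatory cytokines went both ways, more of them lower. The interferon list had a median log2 ratio of 1.12 (interval 0.78 to 1.28; 19 of 21 measured members above 0, above all matched random lists), and 0.62 with each neutrophil cluster weighted equally. Rsad2, an antiviral enzyme gene, had 7 and 71 UMIs (3.06), Ifit1 7 and 42 (2.31), Isg15 86 and 185 (0.90) and Ifitm3 283 and 711 (1.12), whereas Cxcl10 was lower (-0.31). 1 cell of the library labelled KC;Ccr1-/- held 60.6% of its Rsad2 UMIs and 1 held 42.9% of those of Ifit1.

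Inflammatory cytokines and NF-kB targets had a median of -0.18 (6 of 18 above). It was -0.033 with each cell weighing the same and -0.35 with a minimum of 500 genes. Cxcl1 (-1.09) and the abundant Il1b (-0.21) and Cxcl2 (-0.25) were lower, but Cxcl2 stood at 0.0016 with each cluster weighted equally. Maturation genes went both ways, with a median of -0.08 (7 of 16 above): the granule gene Ltf was higher (1.50) and Chil3 lower (-1.26). Tumour-associated neutrophil genes had a median of -0.08 (7 of 16 above). Chemokine receptors had a median of -0.66 (2 of 6 above), with Cx3cr1 at -1.55 and Cxcr2, the receptor that brings neutrophils into tissue, at 0.66. Genes of glycolysis and hypoxia had a median of 0.38 (14 of 18 above). The lowest genes by the fixed rule included Gdpd3 (-3.25, from 333 to 40 UMIs), Prdm1 (-1.36), Stap1 (-1.26) and Thbs1, which encodes thrombospondin 1 (-1.25). Fn1 (1.87), Dpt (1.84), Cpxm1 (1.79) and Tnxb (1.52) were on the higher side. Fibroblast RNA was present in this class: 13 of 378 and 13 of 362 neutrophils held 93.6% and 93.2% of the class's fibroblast-marker UMIs. Without them Tnxb was at -0.18 and Dpt at 0.58 (interval -0.77 to 2.09), while Fn1 (1.45, interval 1.01 to 1.94) and Cpxm1 (1.17, interval 0.39 to 2.04) stayed higher. The remaining neutrophils still held 214 and 423 CPM of the fibroblast markers. Fibroblast RNA was thus not fully removed, and its part in the values of Fn1 and Cpxm1 was not tested.

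How did T cells differ? Cytotoxic genes were lower in the library labelled KC;Ccr1-/-. The cytotoxic list had a median of -0.35 (interval -0.46 to -0.21; 5 of 17 above, below all matched random lists), or -0.17 with each cell weighing the same and -0.19 with each cluster weighted equally. Granzyme genes Gzma (531 and 217 UMIs, -2.15) and Gzmb (-1.29) and the chemokine gene Xcl1 (-0.98) were lower, while the transcription factor gene Eomes was higher (0.56). NK-type cells, which sit within this class, made up 7.05% and 4.41% of it, and the NK receptor gene Klrb1c was lower too (-1.03).

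Regulatory T cells made up 44.3% and 41.6% of T cells, gamma delta 9.55% and 9.92%, and CD8 8.18% and 10.2%. Naive cells numbered 44 of 440 and 58 of 635. Each of these ratios had an interval that included 0 on the log2 scale, and 20.9% and 24.7% stayed without a name. Without removal of doublets, regulatory T cells made up 31.9% and 24.1%. Regulatory T cell genes had a median of -0.04 (4 of 12 above), with Foxp3 at -0.09 and Il2ra at -0.50. The median was -0.19 with each cell weighing the same and -0.22 with each cluster weighted equally. A Foxp3 UMI was seen in 36.8% and 33.4% of T cells, or 29.2% and 24.0% after thinning, against 0.0354% and 0.193% of thinned fibroblasts. Median depths were 5238.5 and 6452 UMIs in T cells and 11820 and 23175 in fibroblasts.

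Inhibitory receptor and exhaustion genes had a median of -0.35 (3 of 16 above), which lay at -0.03 among members with at least 100 UMIs. Lag3 (-1.32) and Nr4a3 (-0.52) were lower, while Pdcd1 (0.10) and Ctla4 (0.03) were close to 0. Naive and memory genes had a median of -0.19 (3 of 12 above), chemokine receptors -0.27 (3 of 12 above) and type 2 and type 17 cytokine genes -0.15 (4 of 12 above). In the last list Il22 was higher (18 and 122 UMIs, 1.88, with 61.1% and 49.2% from 1 cell each), Il4 lower (20 and 7 UMIs, -2.27) and Il17a at 0.12. Gdpd3 (ENSMUSG00000030703, chromosome 7, 126766334 to 126775649; 391 and 3 UMIs, -7.61, interval -10.17 to -6.33) was the lowest gene. The gut-homing receptor gene Ccr9 was higher (1.04).

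How did the lesion epithelium differ? Ductal and PanIN epithelial cells of the library labelled KC;Ccr1-/- held more cell cycle transcripts and less of the gastric-type mucous programme, with targets of KRAS and MAPK signalling a little higher. All 18 cell cycle genes lay above 0, with a median log2 ratio of 3.63 (interval 3.15 to 3.98, above all matched random lists), while the summed CPM of the list, mostly from abundant genes such as Hmgb2 and Stmn1, were 293 and 718, a log2 ratio of 1.29. Mki67 had 6 and 454 UMIs (4.89), Top2a 10 and 414 (4.05) and Birc5 11 and 572 (4.38). The mitotic cyclin genes Ccnb2 and Ccnb1 had 0 UMIs in KC and 333 and 169 in the other library, at least 45.5-fold and 23.1-fold higher. Cells with at least 5 UMIs over 9 mitosis genes, a limit chosen after the values were seen, numbered 3 of 192 (1.56%, interval 0.323% to 4.50%) and 37 of 363 (10.2%, interval 7.28% to 13.8%). Median depths of this class were 42262.5 and 50493 UMIs.

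Gastric-type PanIN genes had a median of -0.78 (interval -0.84 to -0.75; 3 of 18 above, below all matched random lists). The gastrokine genes Gkn2 (-3.58) and Gkn1 (-2.77), the mucin gene Muc5ac (-2.32), the trefoil factor gene Tff1 (-2.18) and Cldn18 (-1.53) were lower, and Tff2 less so (-0.64). Muc6, a mucin of deep gastric glands, was higher (0.92). Clca1 (-4.04) and Mucl3 (-3.91) were the lowest genes by the fixed rule. Pyy stood at -3.58, but 95.7% of its KC UMIs came from 1 cell, and with the mitochondrial limit at 10% it was at 0.98.

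KRAS and MAPK targets had a median of 0.47 (interval 0.38 to 0.54; 15 of 16 above), about as large as that of dissociation and stress genes in the same cells (0.42, 19 of 20 above), and ribosomal protein genes were also higher (0.28, 80 of 83 above). Etv4 (1.04), Spry4 (0.97), Ccnd1 (0.57) and Dusp6 (0.46) were higher and Dusp4 lower (-0.31). Normal duct genes had a median of 0.09 (7 of 11 above), and their member Spp1 was higher (1.01). Epithelial cytokines and chemokines had a median of 0.60 (14 of 17 above), with Lcn2 at 1.58 and Il18, which encodes interleukin 18, at -1.69. Complement genes had a median of 0.66 (12 of 13 above). MHC class II genes had a median of 1.78 (10 of 10 above; 1.44 with a gene at 0 set to its bound), led by the invariant chain gene Cd74 (7.38 and 31.2 CPM). Cd74 stood at 8.19 and 19.0 CPM in fibroblasts and 8311 CPM in macrophages of the library labelled KC;Ccr1-/-. Acinar transcripts were also higher in the epithelium, with a median of 0.95. Their summed CPM there, 2970 and 5292, lay far above those in fibroblasts, 27.4 and 42.5, so they do not measure free RNA alone.

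**Figure D3:**
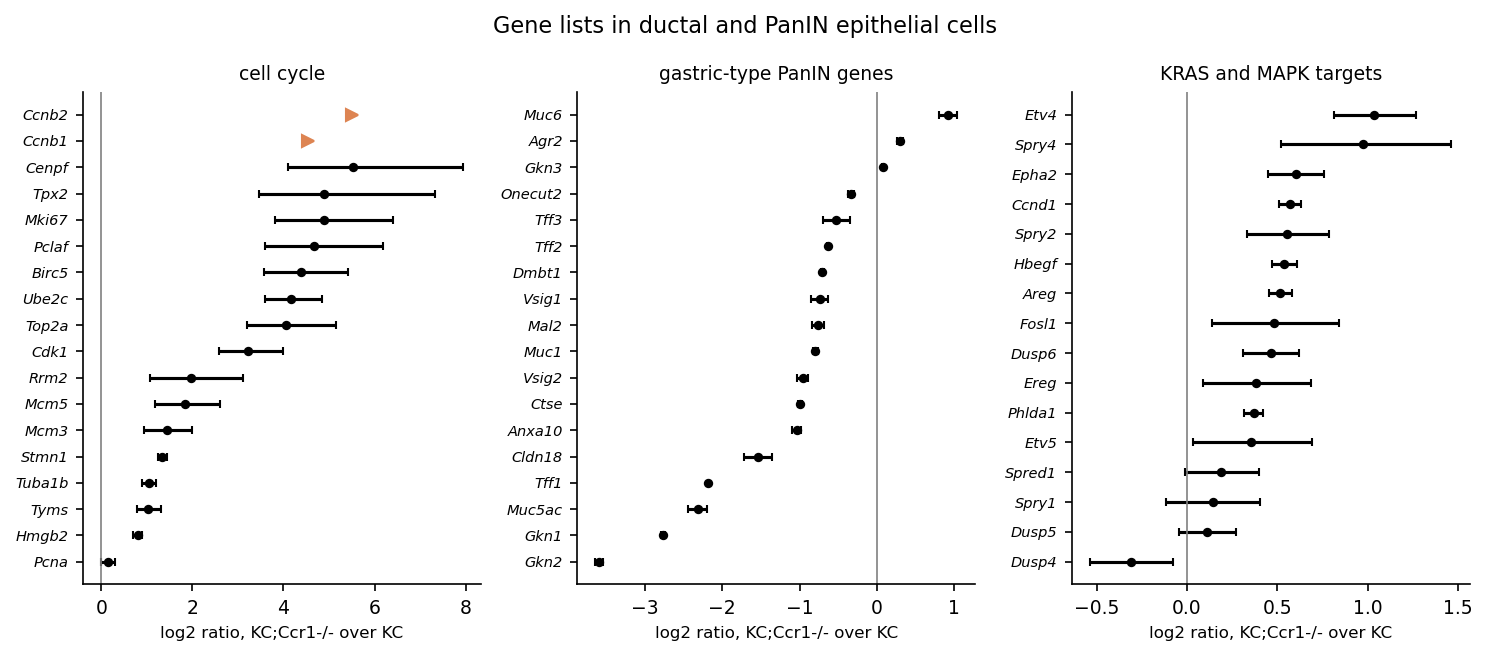
Each point is a gene's log2 ratio, KC;Ccr1-/- over KC, with its exact 95% counting interval, and arrowheads mark lower bounds for the genes with 0 KC UMIs (Ccnb1, Ccnb2). All 18 cell cycle genes lie above 0, 15 of 18 gastric-type genes below 0 and 15 of 16 KRAS and MAPK targets above 0.

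How did tuft cells and B cells differ? The few tuft cells of the library labelled KC;Ccr1-/- (51, against 147) carried more interferon response transcripts, with a median of 0.93 (interval 0.74 to 1.51; 12 of 15 above). Gbp2 (3.01), Isg15 (2.63) and Ifitm3 (2.47) were higher, as was the immunoproteasome gene Psmb8 (2.61), but 1 cell held 80% of the 40 Gbp2 UMIs of that library. MHC class I genes had a median of 0.40 there (8 of 12 above). Dissociation and stress genes were higher there too (0.65), and mitochondrially encoded genes lower (-0.25). Genes abundant in immune cells were higher in the same tuft cells, Cd74 with 11 and 464 UMIs (3.24 and 292 CPM) and Ccl5 with 7 and 279 UMIs (2.06 and 176 CPM). Tff1 was lower (-2.87), as in the epithelium, with Gsta1 (-2.41) and Rgs6 (-1.88). Spp1 (2.11) and Aqp5 (3.58) were higher, with 43.8% and 45.2% of their UMIs in that library from 1 cell each, and a Spp1 UMI was also seen in 3.55% and 23.5% of B cells. In B cells, genes of MHC class II had a median of -0.06 (5 of 12 above). Emb (-2.13), Ikzf2 (-1.86) and Bhlhe40 (-1.16) were lower, while Manf (0.95) and Fosb (0.67) were higher. Of the 18 Emb UMIs of the library labelled KC;Ccr1-/-, 50% came from 1 cell. Foxp3, a T cell gene, was lower in B cells too (30 and 8 UMIs), and an Ikzf2 UMI was seen in only 10.6% and 4.35% of them.

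How did fibroblasts differ? Most myofibroblast, matrix and inflammatory genes were higher in fibroblasts of the library labelled KC;Ccr1-/-, and the class was spread differently over its clusters in each library. Cluster 0 held 38.4% of KC fibroblasts and 18.0% of the others, cluster 1 20.2% and 12.2%, and cluster 4 14.2% and 8.04%, whereas cluster 3 held 5.09% and 30.9% and cluster 9 5.37% and 14.6%. Cluster 2 held similar shares, 16.7% and 16.3%. Median depths were 30964.5 and 24490.5 UMIs in clusters 3 and 9, against 11981.5, 13662, 13838 and 9153 in clusters 0, 1, 2 and 4. Fibroblasts had median depths of 11820 UMIs in KC and 23175 in the other library, and the part of depth in this spread was not tested. With 1 library per group, a cluster mostly of 1 library may be that library, not a type.

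Myofibroblast genes had a median of 0.99 (interval 0.87 to 1.07; 12 of 14 above). It was 0.61 with each cluster weighted equally and 0.55 with each cell weighing the same. The matricellular gene Tnc (2.17) and the contractile genes Tagln (2.16) and Acta2 (1.95) led. Extracellular matrix genes had a median of 0.48 (14 of 21 above), or 0.12 with equal cluster weights and 0.31 with each cell weighing the same. Timp1 (2.15), Col1a1 (0.68) and Col3a1 (0.69) were higher and Dcn lower (-0.54). Inflammatory fibroblast genes had a median of 0.75 (14 of 19 above), or 0.22 with equal cluster weights, although their summed CPM were close, 6239 and 6512. Saa3 (2.93), Ccl7 (1.74), Cxcl1 (1.16) and Il6 (1.01) were higher and Pi16, a gene of adventitial fibroblasts, was lower (-0.52). Of KC Saa3 UMIs, 75.4% came from 1 cell. Cxcl13 stood at 2.62, but 1 cell held 77.3% of its KC UMIs and 1 held 89.9% of those of the other library, and it stood at -0.61 when cells needed 500 genes. Inflammatory cytokines and NF-kB targets had a median of 0.88 (17 of 18 above), complement genes 0.08 (9 of 14 above) and MHC class II genes 0.60 (12 of 13 above). Ifi202b (ENSMUSG00000026535, chromosome 1, 173962568 to 173982744), an interferon-inducible gene, had 1 and 778 UMIs (8.54, interval 6.55 to 14.34). The interferon response list as a whole had a median of only 0.19 in fibroblasts. Hp, which encodes haptoglobin (2.39), Prg4 (2.36) and the EGF receptor ligand gene Ereg (2.58) were higher, while Inmt (-3.17), Art4 (-1.93), the glucocorticoid-induced gene Tsc22d3 (-1.72), the clock output gene Dbp (-1.68) and the hedgehog receptor gene Ptch1 (-1.52) were lower. Across all fibroblast genes with at least 100 UMIs the median was -0.11.

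Which programmes differed in several classes? Interferon response genes had medians of 0.01 in B cells, 0.03 in the epithelium, 0.19 in fibroblasts and -0.16 in T cells, beside the values already given. MHC class I genes had medians of -0.18 in B cells, -0.14 in the epithelium, -0.28 in fibroblasts, 0.19 in neutrophils and -0.09 in T cells. Cell cycle genes had medians of 1.07 in fibroblasts (without the cycling cluster, and with summed CPM of 344 and 313), 1.20 in tuft cells, 0.25 in neutrophils, 0.05 in T cells, 0.03 in macrophages and 0.01 in B cells. Inflammatory cytokines and NF-kB targets stood at 0.48 in the epithelium, 0.30 in tuft cells, 0.27 in B cells and 0.08 in T cells. Genes of glycolysis and hypoxia stood at 0.26 in fibroblasts, 0.13 in B cells, 0.11 in T cells, 0.01 in the epithelium and -0.03 in tuft cells. Dissociation and stress genes were higher in tuft cells (0.65), neutrophils (0.44), the epithelium (0.42), T cells (0.31) and B cells (0.09, or -0.043 without removal of doublets), and lower in fibroblasts (-0.16). In macrophages the interval around -0.07 included 0.

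Lists kept as markers of free RNA and RNA quality differed as well. Acinar transcripts were higher in all 7 classes of the library labelled KC;Ccr1-/-, although no acinar cluster was found. Medians ran from 0.83 in fibroblasts to 3.62 in macrophages (0.25 there with genes at 0 set to their bounds). In the epithelium and tuft cells they are not a measure of free RNA alone. Summed CPM were 2970 and 5292 in the epithelium against 27.4 and 42.5 in fibroblasts, and the member Spink1 was a leading gene of the tuft cluster. With the mitochondrial limit at 10%, macrophages (-7.89) and tuft cells (-0.26) lay on the other side of 0. Mitochondrially encoded genes had medians of 0.39 in macrophages, 0.24 in fibroblasts, 0.07 in neutrophils, -0.01 in T cells, -0.08 in B cells, -0.12 in the epithelium and -0.25 in tuft cells. Other scaling changed the sign in neutrophils (-0.031 with TMM, -0.050 with DESeq2 factors) and in B cells (0.0034 with TMM). Ribosomal protein genes had medians of 0.32 in tuft cells, 0.28 in the epithelium, 0.24 in neutrophils, 0.02 in macrophages, -0.03 in fibroblasts and -0.12 in B and T cells, and in fibroblasts TMM scaling put them at 0.05. Neighbours of Ccr1 on chromosome 9 had medians of -0.25 in T cells, -0.10 in the epithelium, -0.08 in macrophages, 0.05 in tuft cells, 0.08 in fibroblasts, 0.12 in B cells and 0.13 in neutrophils.

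**Figure D4:**
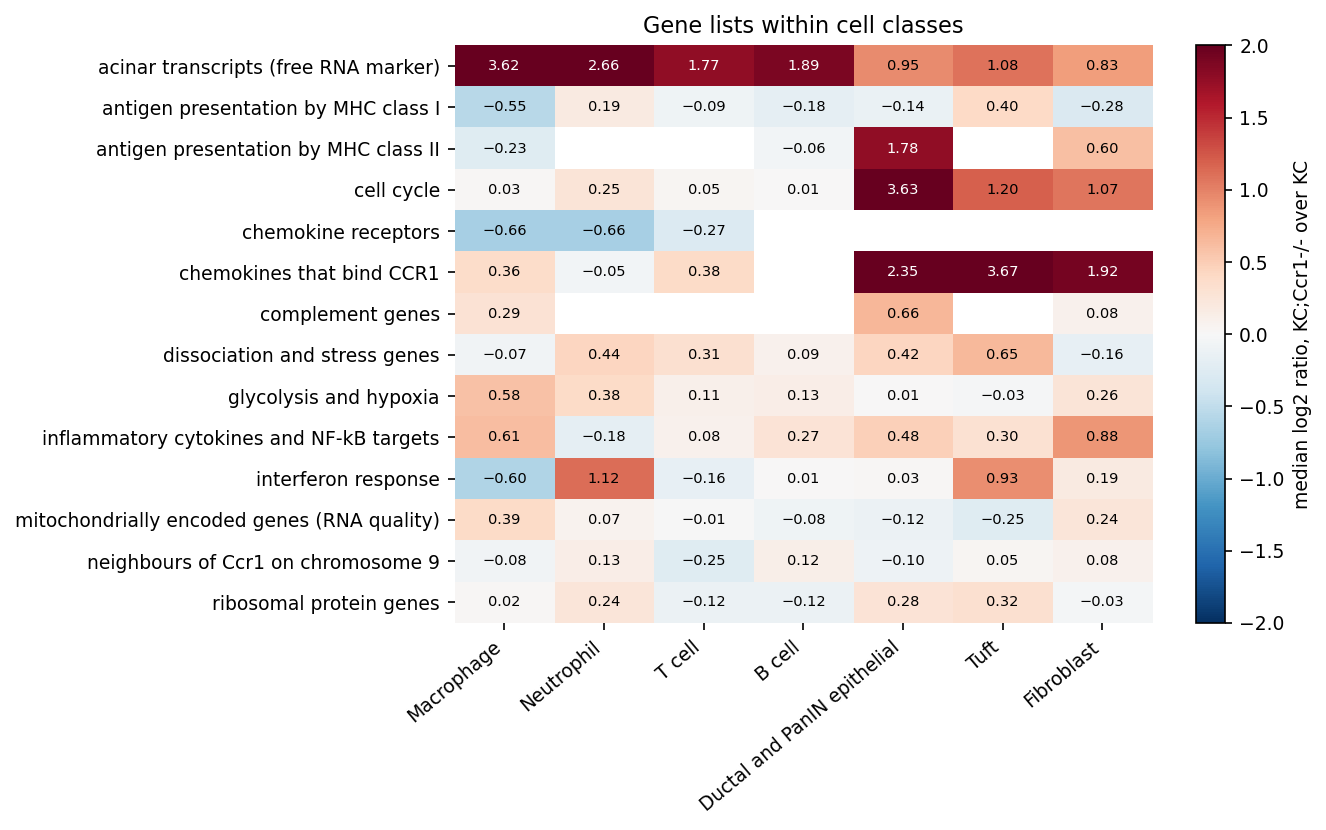
Each square gives the median log2 ratio (KC;Ccr1-/- over KC) of a list measured in at least 3 classes, coloured from -2 (blue) to 2 (red), with larger values at the end of the scale. The cell cycle value in the epithelium (3.63) and the interferon values in neutrophils (1.12) and macrophages (-0.60) can be read there.

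Where did ligands of CCR1 come from? Neutrophils held the most Ccl3, 2525 CPM in KC and 1595 CPM in the library labelled KC;Ccr1-/- (a log2 ratio of -0.66). T cells held Ccl5 at 1557 and 1222 CPM (-0.35, or -0.14 with each cell weighing the same). Dendritic cells held Ccl5 at 1133 and 1698 CPM, with 95.9% of the KC UMIs from 1 cell. Macrophages held Ccl6 at 1189 and 2172 CPM (0.87), Ccl9 at 521 and 607 CPM (0.22) and Ccl4 at 333 and 739 CPM (1.15, or 2.04 with each cell weighing the same, and 60.1% of KC UMIs from 1 cell). Neutrophils held Ccl6 at 1155 and 1012 CPM and Ccl4 at 591 and 570 CPM. In fibroblasts, Ccl7 stood at 25.7 and 85.7 CPM (1.74), Ccl2 at 83.0 and 152 CPM (0.87) and Ccl8 at 5.73 and 14.9 CPM (1.38). Macrophages stood higher for Ccl2 (227 and 321 CPM) and for Ccl8 (74.8 and 30.9 CPM, with 96.8% of KC UMIs from 1 cell), and held Ccl7 at 45.8 and 69.4 CPM (73.7% of KC UMIs from 1 cell). Innate lymphoid cells (39 and 42 cells) stood above fibroblasts, with Ccl7 at 661 and 713 CPM and Ccl2 at 499 and 614 CPM, but single cells held 58.9% and 99.6% of their Ccl7 UMIs and 41.5% and 54.3% of their Ccl2 UMIs. They held Ccl4 at 1696 CPM (56.5% of UMIs from 1 cell) and 222 CPM, and dendritic cells at 1571 and 1035 CPM. The list of these chemokines had a median of 1.92 in fibroblasts (8 of 8 above), but Ccl3, Ccl4, Ccl5, Ccl6 and Ccl9 stood there at 0.133 to 1.28 CPM in KC and 2.10 to 9.97 CPM in the other library, far under their levels in leukocytes. The macrophage gene C1qa was higher in fibroblasts as well (0.853 and 2.01 CPM), as was Cd74, and 53.1% of the fibroblast Ccl5 UMIs of that library came from 1 cell. The list had a median of 2.35 in the epithelium and 3.67 in tuft cells, where Ccl5 and Cd74 were both higher as given above, but epithelial Ccl3 was only 0.967 and 2.74 CPM, far under the level in neutrophils. Medians were 0.38 in T cells, where summed CPM were 1772 and 1442, and -0.05 in neutrophils.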

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

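The tests of explanations in this part were chosen after the results were seen. The mitochondrial limit of 10% and the thinning of cells, from which values are also given here, were planned settings.

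Ccr1 UMIs were counted in neutrophils of the library labelled KC;Ccr1-/-. Free RNA picked up by droplets is argued against: after thinning, 0.0966% of fibroblasts of that library carried Ccr1, against 58.1% of its neutrophils (interval 51.8% to 64.1%). A mix of neutrophils with Ccr1 at the KC level and neutrophils with none, as from a pool of mice with and without the gene, would give 39.7% of cells, and 46.5% at the most. A mix whose Ccr1-bearing neutrophils lie below the KC level was not tested and stays open. Also open are a targeted allele whose transcript is still partly counted and an intact allele with lower expression. Each could give the log2 ratio of -0.98. The allele's structure would be needed to tell them apart, and the labels do not give it.

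Macrophages took more and tuft cells less of the library labelled KC;Ccr1-/-. A lower yield of fibroblasts would move all other classes alike, but among cells other than fibroblasts the log2 ratio was 1.87 for macrophages and -2.08 for tuft cells. The mitochondrial limit is argued against as well, since with no limit and each barcode named on its own the ratios were 2.44 (interval 1.94 to 2.98) and -1.53 (interval -1.92 to -1.15). Digestion and capture cannot be told apart from genotype with 1 preparation per group, and the share of barcodes over the mitochondrial limit, 31.4% against 15.3% in KC, differed between the preparations. Loss of Ccr1 and the number of mice pooled may also account for the shares, and neither was tested.

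Cell cycle transcripts were higher in the epithelium of the library labelled KC;Ccr1-/-. Free RNA of cycling cells reaches every droplet and is argued against as the whole cause, since neutrophils of that library held 27.7 CPM of the mitosis genes (interval 20.8 to 36.2) and the epithelium 144 CPM. Droplets with an epithelial cell and a cycling fibroblast are argued against too: the epithelial cells with at least 5 mitosis-gene UMIs held a median of 30 fibroblast-marker UMIs (interval 17 to 37), other epithelial cells 9, and cycling fibroblasts 1192. Median depths of those epithelial cells were 199618 and 46152 UMIs. A cycling leukocyte in most of these droplets is argued against as well, since 18.9% of them (interval 7.96% to 35.2%) held a Ptprc UMI, against 100% of 34 cycling leukocytes and 9.20% of other epithelial cells. It stays open which lesions each preparation happened to hold, since the KC value of 1.56% rests on 3 cells and 1 mouse. A difference by genotype may be the cause and was not tested.

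Gene lists lay on opposite sides of 0 in different classes, and these differences were not tested. The interferon response was higher in neutrophils (1.12) and lower in macrophages (-0.60), 1.72 apart. MHC class II genes stood at 1.78 in the epithelium and -0.23 in macrophages, 2.01 apart, and MHC class I genes at 0.40 in tuft cells and -0.55 in macrophages, 0.95 apart. With the mitochondrial limit at 10%, macrophages lay above 0 for these 3 lists (0.17, 0.81 and 0.43), so that they no longer lay on opposite sides. Inflammatory cytokines and NF-kB targets stood at 0.88 in fibroblasts and -0.18 in neutrophils, 1.05 apart. Dissociation and stress genes stood at 0.65 in tuft cells and -0.16 in fibroblasts, 0.81 apart. Mitochondrially encoded genes were 0.63 apart between macrophages and tuft cells, and ribosomal protein genes 0.44 apart between tuft cells and T cells.

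Barcodes over the mitochondrial limit, which the main comparisons left out, were named one by one if they had at least 200 genes (399 in KC and 1225 in the other library). Fibroblast-like barcodes made up 38.7% of these in the library labelled KC;Ccr1-/- and 16.8% in KC. Macrophage-like barcodes made up 9.80% and 4.26%.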

How the results depend on the processing

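Leaving out each KC macrophage in turn, leaving out fibroblast-bearing immune cells, adding the unnamed cluster to the macrophages and taking shares of cells other than fibroblasts were chosen after the data were seen. Of 2674 values for 259 results, 2565 kept their sign. By another count, 2159 stayed within the counting interval, 490 moved outside it and 25 reversed. Reversed means a change of sign where the main interval left out 0, and other changes of sign are counted as within or moved. By kind, 1221 of 1242 gene values, 1196 of 1279 list values, 118 of 122 class shares and 14 of 15 T cell subset shares kept their sign. The log2 ratio of shares lay between 1.87 and 2.53 for macrophages, 1.98 and 3.03 for dendritic cells, 1.46 and 2.06 for endothelial cells, and -2.08 and -1.44 for tuft cells. Shares of cells other than fibroblasts gave 1.87 for macrophages, 1.46 for endothelial cells, 0.36 for the epithelium, -0.028 for T cells, -0.62 for neutrophils, -0.85 for B cells and -2.08 for tuft cells. The epithelial gastric-type list (-0.83 to -0.69) and cell cycle list (2.91 to 3.72) kept their direction under 11 of 11 alternatives. Macrophages and monocytes together, and shares without acinar and erythroid cells, gave no value because no such cluster was found. CD4 T cells were named only at resolution 0.5 (81 and 129 cells). At resolution 2.0 only 19 and 28 T cells were named regulatory. Unless a setting itself shows the cause, the cause was not tested.

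With the mitochondrial limit at 10%, the macrophage class took in other cells (45 and 184). Its medians were then 0.50 for immunosuppressive, -0.71 for resident, 0.85 for monocyte, 0.81 for MHC class II, 0.43 for MHC class I, 0.17 for interferon, 1.55 for inflammatory, 0.36 for chemokine receptor and -7.89 for acinar genes, with Lyz1 at 1.20 and Tnf at 0.41. Tuft acinar transcripts stood at -0.26 and epithelial Pyy at 0.98. Leaving out 1 KC macrophage gave up to -0.73 for resident, -0.27 for MHC class I and 0.91 for inflammatory genes. Without fibroblast-bearing cells, resident genes stood at -0.59, Mmp3 at -1.07, Plpp3 at -2.66 and Sfrp2 at -1.50 in macrophages and Tnxb at -0.18 in neutrophils. Mmp3 (1 and 3 UMIs) and Sfrp2 (1 and 2 UMIs) then had too few counts to give a direction. Members with at least 100 UMIs gave -1.002 for resident genes and -0.027 for inhibitory receptors in T cells.

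With TMM and DESeq2 scaling in turn, fibroblasts gave 0.052 and 0.064 for ribosomal protein, 0.83 and 0.85 for inflammatory fibroblast, 1.07 and 1.08 for myofibroblast, and 0.56 and 0.58 for matrix genes. Neutrophils gave -0.28 and -0.29 for inflammatory and -0.031 and -0.050 for mitochondrial genes, and B cells gave 0.0034 for mitochondrial genes with TMM. The reduced total gave -0.69 for gastric-type genes and 0.56 for KRAS and MAPK targets. With each cell weighing the same, medians were 2.91 for the epithelial cell cycle, 0.55 for myofibroblast, 0.31 for matrix, 0.88 for macrophage inflammatory, -0.033 for neutrophil inflammatory, -0.17 for cytotoxic and -0.19 for regulatory T cell genes. Ligands then stood at -0.43 for Ccl3, 2.04 for Ccl4, -0.14 for Ccl5, 0.59 for Ccl6, 1.96 for Ccl7 and 1.05 for Ccl2. With clusters weighing the same, medians were 0.22 for inflammatory fibroblast, 0.61 for myofibroblast, 0.12 for matrix, 0.62 for neutrophil interferon, -0.25 for neutrophil inflammatory, -0.19 for cytotoxic and -0.22 for regulatory T cell genes, and Cxcl2 in neutrophils stood at 0.0016.

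A minimum of 500 genes gave 0.19 for the neutrophil share, 0.60 for inflammatory fibroblast genes, -0.35 for neutrophil inflammatory genes and -0.61 for fibroblast Cxcl13. Centring per library gave 0.64 for myofibroblast genes, 0.45 for matrix genes and 0.11 for macrophage Lyz1. Without removal of doublets, Lyz1 stood at 0.023, macrophage inflammatory genes at 0.47, B cell stress genes at -0.043 and the regulatory T cell share at -0.41. Naming cell by cell gave 0.80 for the T cell share. As shares of immune cells, neutrophils stood at -0.51, T cells at 0.083 and B cells at -0.74. Thinning put the share of cells with Ccr1 at 58.1% in neutrophils and 10.9% in macrophages of the library labelled KC;Ccr1-/-, and at 18.5% in KC macrophages.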

Other observations

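A pair of genes, Gdpd3 and Ifi202b, separated the libraries in several cell types. Gdpd3, which encodes a phospholipase, had 66 KC UMIs and 0 of the other library in B cells, 65 and 0 in plasma cells, and 391 and 3 in T cells. The separation was not complete in every class. Without fibroblast-bearing cells, Gdpd3 had 326 and 39 UMIs in neutrophils and 45 and 61 (158 and 29.5 CPM) in macrophages. Ifi202b, an interferon-inducible gene, had 1 and 778 UMIs in fibroblasts and 0 and 90 in mesothelial cells. The interferon response list had a median of only 0.19 in fibroblasts. With 1 library per group, a difference between the mice in either gene cannot be told apart from one by Ccr1 genotype. Neither was tested.

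Some genes of the circadian clock, chosen after their values were seen, differed in fibroblasts. Tef, Per1, Per2, Nr1d2 and Npas2 were looked up as well, and their values are not given here. Hlf (-2.30), Dbp (-1.68), Ciart (-1.62), Per3 (-1.38) and Nr1d1 (-1.08) were lower in the library labelled KC;Ccr1-/-, while Arntl, which acts in the opposite arm of the clock, was higher (1.03). Dbp was also lower in neutrophils (-2.33) and the epithelium (-0.57). The cause of the clock gene differences was not tested.

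Ins2, the insulin gene of endocrine cells, stood at 25.4 and 4.11 CPM in neutrophils and at 12.8 and 2.996 CPM in fibroblasts. Cycling cells, by the limit of 5 mitosis-gene UMIs, numbered 0 of 2945 and 32 of 2115 in fibroblasts, 0 of 44 and 11 of 178 in endothelial cells, 4 of 440 and 14 of 635 in T cells, and 1 of 28 and 12 of 151 in macrophages. The fibroblast counts leave out the cycling cluster that stayed without a name (10 and 54 cells), which scored highest for fibroblast markers. The limit is a fixed count that deeper cells pass more easily, and median depths of fibroblasts were 11820 and 23175 UMIs. As CPM, the mitosis genes stood at 5.81 and 19.2 in fibroblasts. Of the 399 and 1225 barcodes over the mitochondrial limit that had at least 200 genes, tuft-like ones made up 20.3% in KC and 3.84% in the other library, and epithelial-like ones 42.4% and 29.1%.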
